A study of Mus musculus with 3 samples.

How the data were processed

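Circular chromosome conformation capture (4C) joins DNA ends that lie close together in fixed nuclei and then amplifies, by inverse PCR from a chosen bait fragment, whatever was ligated to it. Here the baits lay in the mitochondrial genome (mtDNA) of mouse cortical astrocytes cultured from pups of postnatal day 1 to 2, fixed in 2% paraformaldehyde and cut with the restriction enzyme MspI, per the labels' protocols. The 5 baits came from mtDNA positions 3361 to 8410, a region with the ND1, ND2, CO1, CO2, ATPase8 and ATPase6 genes, per the labels' protocols. There were 3 libraries: 1 that was digested and not ligated, which per the series' design text serves to find products of mispriming, and 2 technical replicates that were digested and ligated. Capped blocking primers against the fragments next to each bait were used to lower their amplification, per the series' design text.

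The deposited values were read counts per MspI fragment, 1 table for each of the 5 baits with 1 column per library, per the file headers and the values, which were whole numbers with different totals. The tables were not normalized. Fragment coordinates were on mouse build GRCm38, per the chromosome accessions in the files. Bowtie 1.0.0 was named in the submitters' processing notes without a role. Its settings, and the treatment of reads with several matches in the genome, were not given in the sources used here. A further deposited column gave the number of nuclear mitochondrial insertions (NUMTs, nuclear copies of mtDNA) the authors assigned to each fragment. Every listed fragment had at least 1 read or a NUMT, so fragments without reads were not listed. The labels did not say which bait belonged to which table, and the tables are called bait 1 to bait 5 in their deposited order. Coordinates are printed as deposited. The mtDNA fragments started at 0, so positions may be 1 base below those of a genome browser.

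Each bait was analysed on its own. Shares of reads on nuclear fragments were given with exact Clopper-Pearson 95% intervals, and a share of 0 with the upper limit that 3 counts allow. CPM values are reads scaled to the total of a library in that table. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. The replicates were technical, so SDs and p-values over libraries measure only the spread between 2 technical replicates, not between cultures or animals. Ligated and unligated libraries were compared per nuclear fragment with edgeR's quasi-likelihood test on the deposited read counts, using table totals as library sizes, fragments with at least 10 reads over the 3 libraries, and Benjamini-Hochberg adjustment at 0.05. DESeq2 was run as an alternative.

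A reproducible fragment was a nuclear fragment with at least 1 read in both ligated replicates and 0 in the unligated library, which is a definition and does not by itself show a contact. Reproducible fragments within 10 kb were merged to 1 interaction for the chromosome test, since touching fragments often carried equal read numbers: in replicate 2, 54.6% of touching pairs with reads had equal counts in bait 1 and 54.6% in bait 5. Fisher tests over fragments take each fragment as independent and so give p-values that are too small. The design had assumed an MspI digest of the whole genome and a full annotation. Neither was used here, so the 175390 nuclear fragments listed in any of the 5 tables stood in for the digest, and exons, introns and promoters were not tested. Gene positions came from a RefSeq table of build GRCm38.p6 that holds gene spans without strand or exons.

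The overlap of the replicates and the overlap between baits were tested with Fisher's exact test, two-sided, beside the overlap of independent lists. Numbers of interactions per chromosome were set against the numbers of listed fragments, with a chi-square statistic whose p came from 100000 multinomial draws, and with an exact binomial test for each of 21 chromosomes, adjusted over chromosomes and baits. Overlap with genes was tested with Fisher's exact test, two-sided, where at least 1 base counted. A gene of a list counted as contacted when a reproducible fragment of any bait lay in it or within 2 kb. Lists were tested against 21887 protein-coding genes with a one-sided Fisher's exact test, adjusted over 10 lists, and against 10000 random lists matched on deciles of the number of listed fragments per gene.

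The 10 lists, the tests, the alternative settings and the rule for named fragments were fixed before the data were examined. The lists were nuclear subunits of oxidative phosphorylation (OXPHOS), the mitochondrial ribosome and translation, mtDNA maintenance and transcription, mitochondrial biogenesis and dynamics, genes of astrocytes, neurons, oligodendrocytes and microglia, cytosolic ribosomal proteins, and long neuronal or synaptic adhesion genes. The rule named, for each bait, the 5 reproducible fragments with the most reads in the lower of the ligated replicates, the genes of the 4 mitochondrial lists contacted by 2 or more baits (at most 15), every fragment of 4 or more baits (at most 10), and the chromosomes with the highest and lowest ratio. There was no fragment of 4 or more baits, so fragments of 3 baits are named and were chosen after their values were seen, as were list members other than those contacted by 2 or more baits. A few items that the rule names are not reported here.

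The alternative settings fixed in this way were minimums of 2 and 10 reads per fragment, each ligated replicate left out, the unligated library ignored or allowed up to 0.1 of the mean ligated rate, DESeq2, TMM factors, other filters for edgeR, chromosome length as expectation, merging within 100 kb or none, autosomes only, a shared window of 10 kb, and other gene windows. Alternatives chosen after seeing the data left out NUMT fragments, left out 3 multi-copy loci, used the midpoint of a fragment, took all fragments listed in any table as the background of the replicate overlap, with and without NUMT fragments, or left out fragments of recurrent length, for the overlap with genes also together with the minimums of 2 and 10 reads. A recurrent length was a fragment length held by at least 50 listed fragments and by at least 3 times the median of lengths within 20 bp, as copies of a repeat would give. There were 41 such lengths, with 45301 fragments (25.8% of those listed).

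The edgeR, chromosome and gene list steps were tested on simulated data. With 64-fold changes in 200 fragments at a dispersion of 0.1, the edgeR step called 98.0% of them among 14653 fragments of bait 1, 54.5% among 10372 of bait 2, 100% among 1337 of bait 3 and 99.5% among 21497 of bait 5. At a dispersion of 1 it called 0% in each of these 4 baits, among 11958, 8804, 1127 and 18360 fragments, and the common dispersions of the real tables lay between 1.85 and 11.2. The chromosome step called a 2-fold excess on X in 99 of 100 simulations with 900 interactions, which were drawn without clusters or merging. The list step found a 6-fold excess in odds in 100% of 200 simulations with 60 genes among 21900. These simulations gave every gene outside the list the same probability of contact and used an unadjusted p. They did not cover smaller excesses, shorter lists or the matched random lists. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.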

Results

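The data comprised read counts per MspI fragment for 5 mtDNA baits in mouse cortical astrocytes, glial cells of the cerebral cortex grown as secondary cultures. Each bait was amplified from 1 library that was digested and not ligated and from 2 ligated technical replicates. Depth differed widely between libraries and baits. The unligated library held 28084, 6718, 48419, 63 and 110271 reads for baits 1 to 5, replicate 1 held 254906, 293359, 257471, 2614 and 985544, and replicate 2 held 693279, 863956, 322092, 2662 and 1679987. Bait 4 was therefore too shallow for most comparisons.

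How much of the signal joined mtDNA to nuclear DNA was asked first. After ligation, nuclear fragments of build GRCm38 took 55.7% ± 28.7 of the reads of bait 1, 45.6% ± 39.0 of bait 2, 16.8% ± 9.61 of bait 3, 6.68% ± 4.90 of bait 4 and 33.8% ± 27.3 of bait 5 (mean ± SD, n = 2). Replicate 1 had 35.4%, 18.0%, 10.0%, 3.21% and 14.5%, and replicate 2 had 76.0%, 73.2%, 23.6%, 10.1% and 53.1%. Without ligation the nuclear share was 1.21% for bait 1 (95% interval 1.09 to 1.35%), 1.14% for bait 3 (1.049 to 1.24%) and 0.965% for bait 5 (0.908 to 1.02%), and both ligated replicates lay above it in each of these baits. Bait 2 differed, with 67.3% nuclear reads in its unligated library (66.1 to 68.4%), of which 4232 of 4519 reads lay on a NUMT fragment inside Myo3a, a gene for an unconventional myosin. Without NUMT fragments the ligated shares were 55.3% ± 29.2, 43.4% ± 41.6, 9.63% ± 12.8, 4.37% ± 5.08 and 33.4% ± 27.6 in baits 1 to 5 (n = 2). Replicate 1 then had 34.7%, 14.0%, 0.610%, 0.784% and 13.9%, and replicate 2 had 75.9%, 72.8%, 18.7%, 7.96% and 52.9%, so the means rested mostly on replicate 2, above all in baits 3 and 4. The unligated shares were 0.790%, 10.9%, 0.0292%, 0 and 0.823%. Bait 4 had 1 nuclear read among 63 in its unligated library, and 0 without NUMT fragments, which allows a share of up to 4.84%. The ligated replicates themselves differed far more than counting error: nuclear reads of replicate 2 were 5.84, 12.0, 2.95, 3.21 and 6.26 times those of replicate 1 in baits 1 to 5, while mtDNA reads stood at 1.01, 0.963, 1.06, 0.945 and 0.934 times. With 1 unligated library, no test between the conditions was made for the shares.

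**Figure D1:**
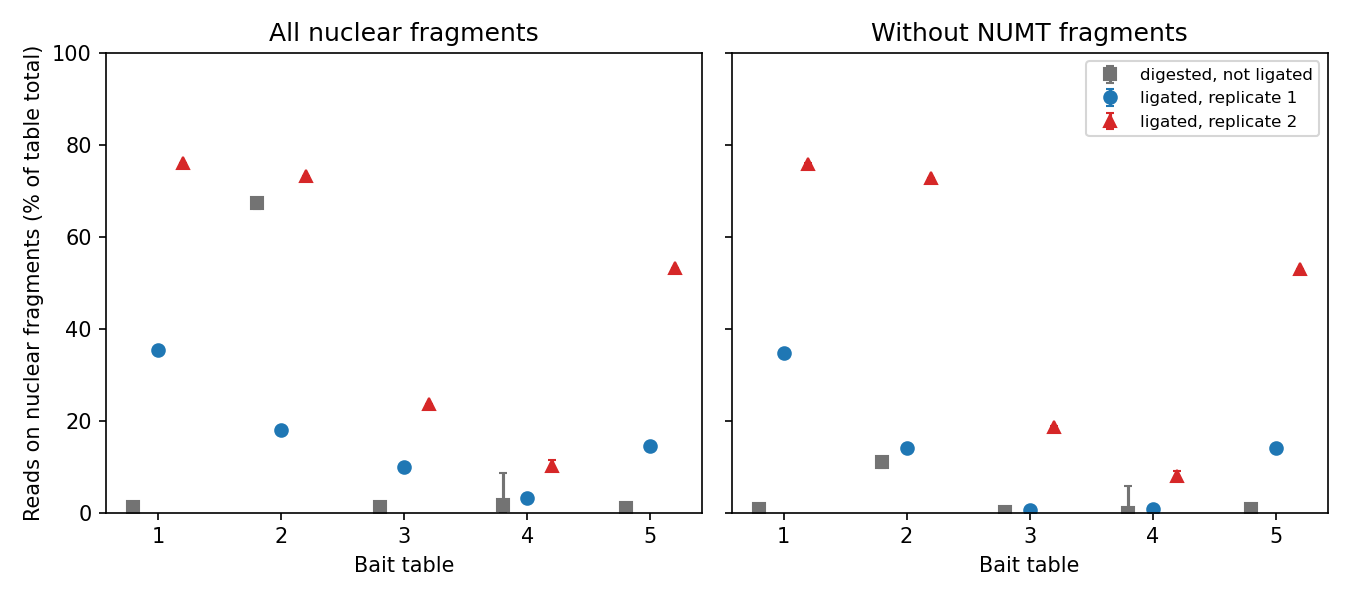
Reads on nuclear fragments as a percent of the table total (y axis) for each bait table (x axis), for the unligated library (grey squares), ligated replicate 1 (blue circles) and ligated replicate 2 (red triangles), with exact 95% binomial intervals as bars, with NUMT fragments (left) and without them (right). Bait 2 is the exception among unligated libraries, at 67.3% with NUMT fragments and 10.9% without.

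Within mtDNA, reads gathered on short fragments of the gene for cytochrome c oxidase subunit I (COX1). The 387-bp COX1 fragment at 5726 to 6112 took 67.5% ± 0.811 of mtDNA reads in bait 1 and 66.0% ± 3.86 in bait 2 after ligation. The 114-bp COX1 fragment at 6275 to 6388 took 50.9% ± 5.37 in bait 3 and 94.6% ± 0.431 in bait 5, and the 162-bp COX1 fragment at 6113 to 6274 took 86.2% ± 3.13 in bait 4 (n = 2 throughout). The unligated libraries had their highest mtDNA share at the same COX1 fragment in baits 2 to 5, at 83.9%, 89.1%, 95.2% and 99.8%, whereas that of bait 1 had 70.8% at a 68-bp ND1 fragment at 3333 to 3400. Other mtDNA fragments took larger shares after ligation. In bait 1 the ND1 and 16S rRNA (mt-Rnr2) fragment at 2520 to 3332 rose from 0.123% to 3.53% ± 0.523 of mtDNA reads, and the 12S rRNA (mt-Rnr1) fragment at 0 to 133 from 0.00721% to 0.398% ± 0.00771, both by more than the SD of the replicates, although the unligated library held 34 and 2 reads there. The 7342-bp fragment at 8401 to 15742, which runs from ATP6 to CYTB, held 0 to 2 ligated reads in baits 1 to 4, and 45 and 21 in bait 5, against 48 unligated reads in that bait.

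**Figure D2:**
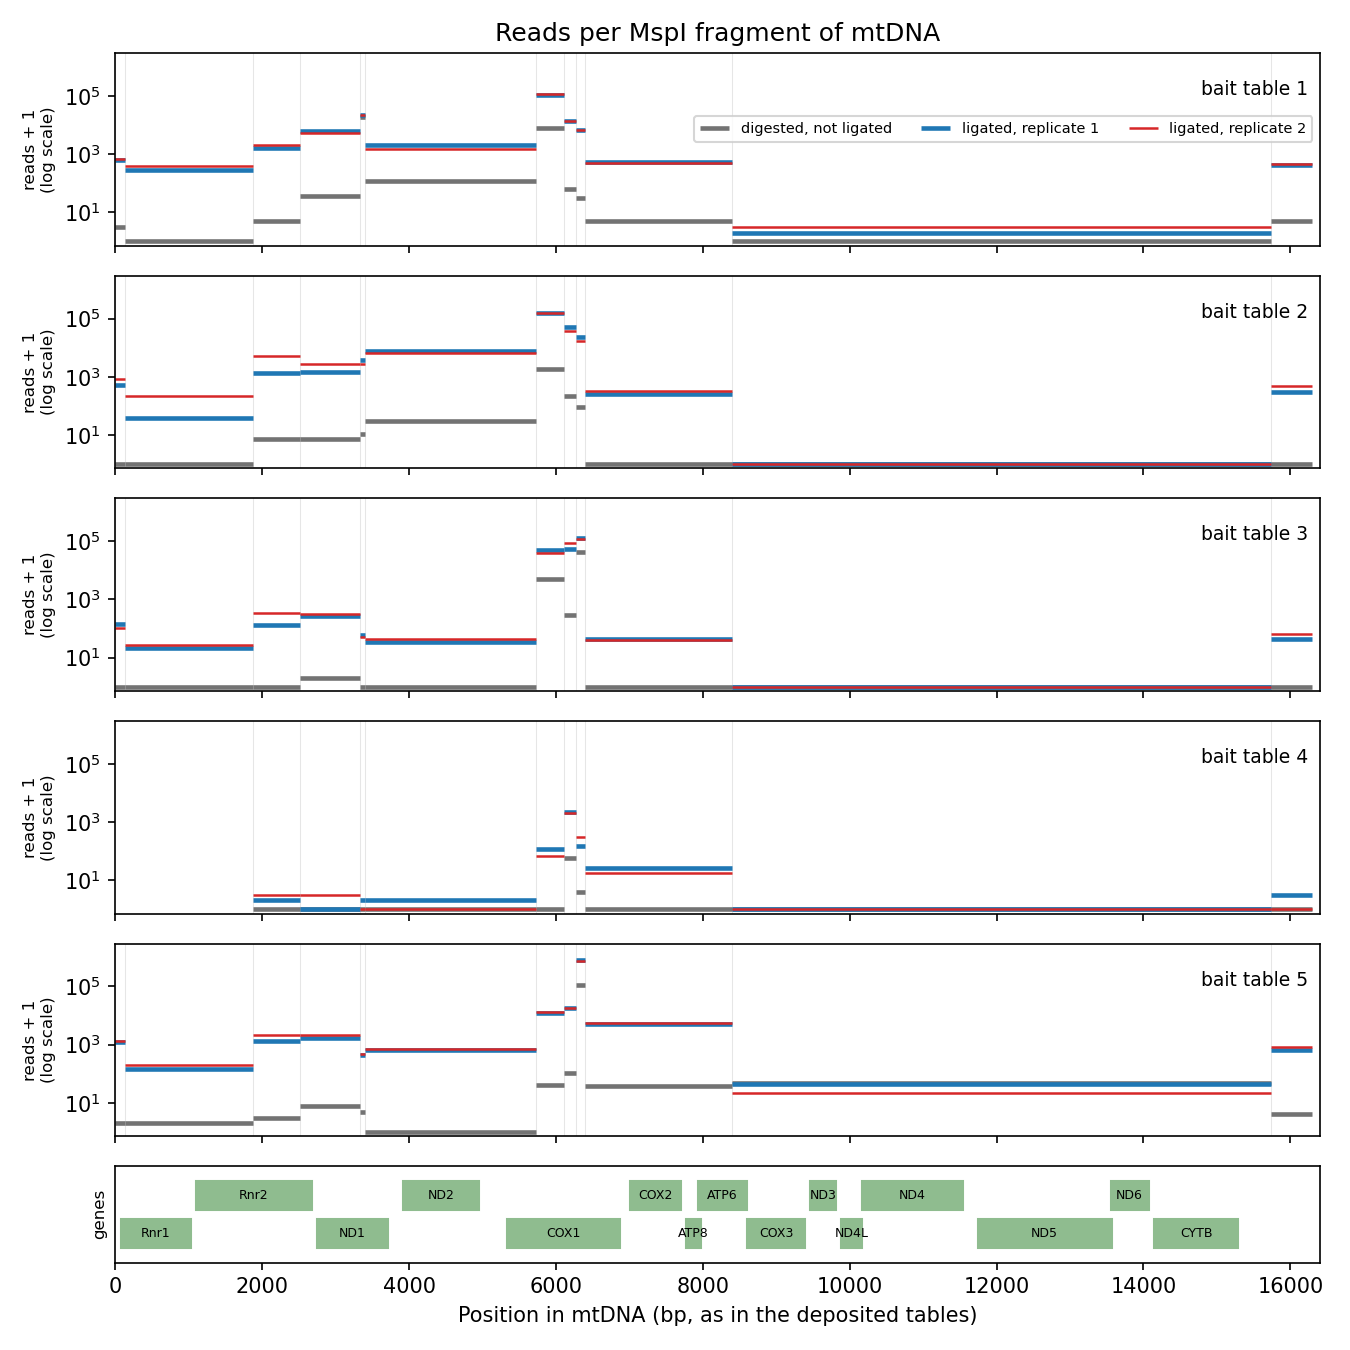
Reads plus 1 (y axis, log scale) on each MspI fragment along mtDNA (x axis, bp) for the 5 bait tables, with the unligated library in grey, ligated replicate 1 in blue and ligated replicate 2 in red, above a map of the mtDNA genes. Each horizontal line spans a fragment, and the highest lines lie on COX1 fragments between 5726 and 6388, except in the unligated library of bait 1.

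The nuclear fragments with the most reads held NUMTs. In bait 3 the 387-bp Myo3a fragment on chromosome 2 at 22588861 to 22589247 had 23124 and 18386 reads in the ligated replicates and 524 in the unligated library. Its neighbour in Myo3a at 22589248 to 22591652 had 9966 and 8140 ligated and 4232 unligated reads in bait 2. In bait 5 the leading NUMT fragment was on chromosome 1 at 24614176 to 24619768, in the pseudogene Gm10925, with 4549 and 5175 ligated reads and 139 unligated. Another locus, without a gene, lay on chromosome 12 at 97061496 to 97062857, with 704 and 849 ligated reads and 1 unligated read in bait 5. The Myo3a fragments of 114, 162 and 387 bp have exactly the lengths of the COX1 fragments at 6275, 6113 and 5726, in opposite order. In bait 3 the Myo3a fragment of 387 bp held 45.5% as many reads as the COX1 fragment of that length in each ligated replicate, and 10.7% in the unligated library. The same pair stood at 0.0462% and 0.0556% in replicates 1 and 2 of bait 1, 1.93% and 2.37% in bait 2, 0 and 0 in bait 4, and 0.0236% and 0.00772% in bait 5. NUMT reads of replicate 2 were 0.834, 0.940, 0.803, 0.984 and 1.12 times those of replicate 1 in baits 1 to 5, close to the mtDNA ratios, whereas other nuclear reads stood at 6.01, 15.8, 39.7, 10.4 and 6.48 times. NUMT fragments held 94.5% of the nuclear reads of replicate 1 in bait 3 (exact 95% interval 94.2 to 94.8%) and 25.7% of those of replicate 2 (25.4 to 26.0%).

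**Figure D3:**
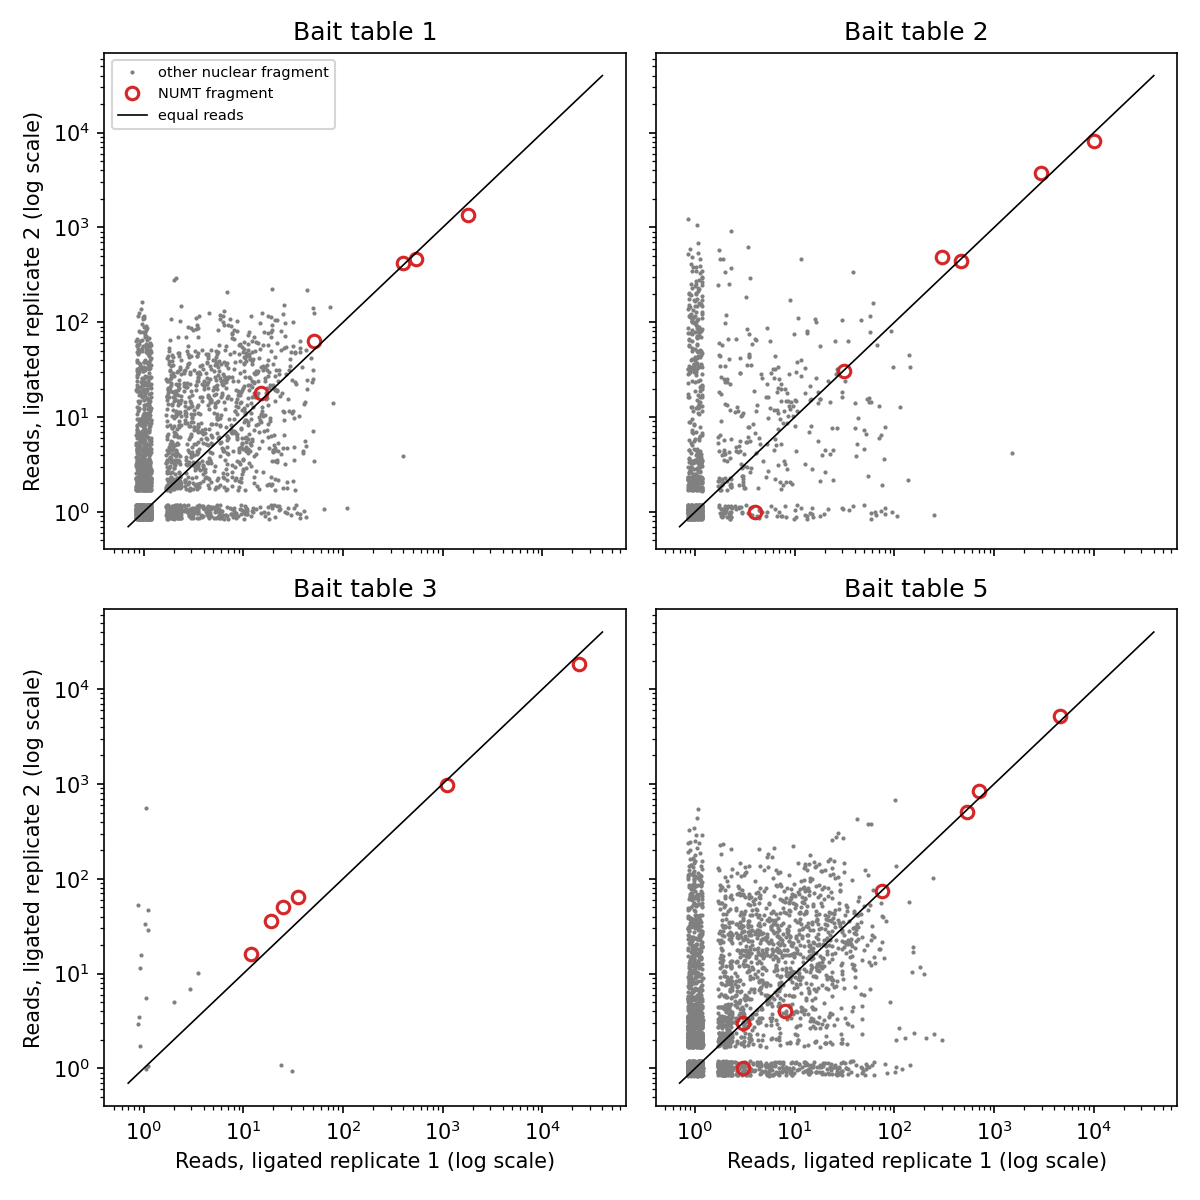
Reads in ligated replicate 1 (x axis, log scale) against ligated replicate 2 (y axis, log scale) for each nuclear fragment seen in both replicates of baits 1, 2, 3 and 5, where grey points are fragments without a NUMT (spread slightly to show overlapping points) and red circles are NUMT fragments. NUMT fragments with many reads lie near the black line of equal reads, as in bait 3, where the highest had 23124 and 18386 reads.

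Which nuclear fragments were enriched by ligation was tested against the unligated library. The 387-bp Myo3a NUMT fragment of bait 3 had the lowest unadjusted p (0.000275), at 10822 CPM unligated and 73448 ± 23143 CPM ligated (SD, n = 2). Its log2 fold change was 2.76, with an adjusted p of 0.423 in edgeR. The smallest adjusted p in edgeR was 0.188, for the Gm10925 NUMT fragment of bait 4, where 2 fragments were tested (0 CPM unligated, 22188 and 22539 CPM ligated). With edgeR, 0 of 16326, 11408, 1537, 2 and 23498 tested fragments passed in baits 1 to 5. At an unadjusted p under 0.05 the counts were 0, 0, 1, 0 and 0, and DESeq2 called 0 in baits 1, 2, 3 and 5. Without the filter on low counts, edgeR called 1 fragment of 10449 in bait 3, the same Myo3a fragment, at an adjusted p of 0.000403. Common dispersions were 8.80, 9.59, 11.2, 1.85 and 10.1, above the level of 1 at which simulated 64-fold changes were not found.

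Without calls from that test, fragments seen in both ligated replicates and not in the unligated library were taken as candidate nuclear contacts. There were 3050 in bait 1, 1091 in bait 2, 21 in bait 3, 2 in bait 4 and 4714 in bait 5. The unligated library serves to find mispriming and cannot show ligation of ends that did not lie close together. An E. coli ligation control is mentioned in the labels, but no counts for it were found in the data used here. In bait 1 the reproducible fragments with the most reads were a fragment without a gene on chromosome 2 at 98666262 to 98666502 (87 and 149 reads in replicates 1 and 2) and 1 on chromosome X at 151098493 to 151098784, near Fgd1 and Tsr2 (59 and 164). They were followed by chromosome 3 at 8897648 to 8897912 in Mrps28, a protein of the small mitochondrial ribosomal subunit (55 and 109, or 186 ± 41.4 CPM, SD, n = 2) and chromosome 17 at 17838124 to 17838362 in Spaca6 and Has1 (51 and 36). Bait 2 was led by Nr4a3, an orphan nuclear receptor gene, with fragments on chromosome 4 at 48047526 to 48047860 (102 and 83 reads) and 48047897 to 48048129 (76 and 68). Next in bait 2 were Mocs1, which acts in molybdenum cofactor synthesis, on chromosome 17 at 49428537 to 49428882 (58 and 168), and touching fragments on chromosome 1 at 58973985 to 58974057 in Stradb and Trak2, a kinesin adaptor of mitochondrial transport (49 and 102 each). Bait 3 had the chromosome 12 NUMT (35 and 65 reads), the Myo3a NUMT fragments at 22589248 (25 and 50) and 22588699 (19 and 36), and fragments on chromosome 19 at 47338865 to 47339325 in Sh3pxd2a (4 and 10) and 54045383 to 54045458 in Adra2a (3 and 7). Both fragments of bait 4 held NUMTs, in Gm10925 (58 and 60 reads) and Myo3a (2 and 3). Bait 5 was led by Ccnd3, which encodes cyclin D3, on chromosome 17 at 47595820 to 47596133 (113 and 161 reads, 105 ± 13.3 CPM). Then came the ribosomal RNA pseudogene Rn18s-rs5 at 39847632 to 39847871 (89 and 699) and the neighbouring AY036118 at 39848471 to 39848525 (146 and 67), both on chromosome 17, Tnrc6a on chromosome 7 at 123068837 to 123069537 (65 and 88), and Cmss1 and Filip1l on chromosome 16 at 57391516 to 57391537 (62 and 409).

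Depth limited what the absence from the unligated library shows. At their mean ligated rate, 30, 1, 6, 0 and 213 of these fragments in baits 1 to 5 would have been due at least 3 unligated reads, so for the others absence could not be separated from too few reads. Requiring 2 reads in each ligated replicate left 928, 260, 6, 2 and 1243 fragments. Replicate 1 alone held 19100, 6079, 251, 23 and 22422 fragments without unligated reads, and replicate 2 alone held 52110, 51380, 10202, 168 and 66639. The leading fragments of the baits were above 1 read in both replicates, but the SDs of Has1 in bait 1 (126 ± 105 CPM), Nr4a3 in bait 2 (222 ± 178 CPM) and Rn18s-rs5 in bait 5 (253 ± 230 CPM, n = 2 each) were nearly as large as their means.

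Whether the ligated replicates found the same nuclear fragments was asked next. They shared 3063 fragments in bait 1, 1117 in bait 2, 24 in bait 3, 2 in bait 4 and 4756 in bait 5, which was 16.0%, 18.3%, 9.30%, 8.70% and 21.1% of the fragments of replicate 1. Myo3a and the other NUMT loci carried 99.7% and 96.4% of the reads on shared fragments of bait 3 in replicates 1 and 2, and 18.9% and 7.12% in bait 1. Against all listed nuclear fragments the overlap was 0.537, 0.621 and 0.552 times that of independent lists in baits 1, 2 and 5, and 1.60 times in bait 3 (24 against 15.0, Fisher's exact p = 0.0229). Without NUMT fragments bait 3 had 18 against 14.7 (1.23 times, Fisher's exact p = 0.346). The fragments of the bait table as background gave 0.210, 0.201, 0.0966, 0.183 and 0.269 times. Both backgrounds hold only fragments that some library detected, which lowers such ratios by construction, so only comparisons between pairs of libraries on the same background are informative. Over baits 1, 2 and 5 without NUMT fragments, on all listed fragments, different baits of the same ligated library gave means of 0.619 (replicate 1) and 0.621 (replicate 2), and different baits of different libraries 0.523. Over these baits, replicates of the same bait overlapped 1.02 ± 0.0253, 1.19 ± 0.0478 and 1.053 ± 0.0170 times as much as replicates of different baits (± SE from leaving out each chromosome).

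The series title asks whether the contacts are non-random, which was tested over chromosomes. The Y chromosome had 1.98 times its share of interactions in bait 1 (35 against 17.7, interval 1.38 to 2.75, adjusted exact binomial p = 0.00755) and 2.67 times in bait 5 (74 against 27.7, interval 2.10 to 3.34, adjusted exact binomial p = 1.62e-11). The X chromosome had 1.37 times its share in bait 5 (278 against 203, interval 1.22 to 1.54, adjusted exact binomial p = 9.41e-06). The interactions were merged, but the listed fragments behind the expectation were not. This can lower the ratios of chromosomes where reproducible fragments cluster and raise those of the others. The lowest ratios were those of chromosome 19 in bait 1 (0.810), Y in bait 2 (0.775), chromosome 3 in bait 3 (0 of 18 interactions, tied with chromosomes 5, 8, 9, 14, 18 and Y) and chromosome 5 in bait 5 (0.829), and none of these passed, nor did the highest of bait 2 (X, 1.29) and bait 3 (chromosome 19, 6.41 from 3 interactions). Over all chromosomes the multinomial p was 0.00124 for bait 1 (2374 interactions), 0.478 for bait 2 (868), 0.304 for bait 3 (18) and 1e-05 for bait 5 (3729), the last being the smallest the draws can give. On autosomes only, the multinomial p was 0.0956 in bait 1 and 0.103 in bait 5. With at least 2 reads per fragment it was 0.232 in bait 5 and 0.00781 in bait 1, but X then stood at 0.4996 times its share in bait 1 (19 against 38.0, exact binomial p = 0.000794) and 0.579 times in bait 5 (29 against 50.1, p = 0.00134), and Y held 1 and 4 interactions. At this minimum the expectation still came from listed fragments of any read number. With at least 10 reads the multinomial p was 0.715 in bait 1 and 0.00734 in bait 5, and without fragments of recurrent length it was 0.698 and 3e-05. The ratios without recurrent lengths were 1.76 for Y in bait 1 (exact binomial p = 0.0537), 1.16 for X in bait 5 (p = 0.156) and 3.11 for Y in bait 5 (p = 1.79e-07). Against chromosome length, X in bait 5 stood at 1.19 times its share and no longer passed (adjusted exact binomial p = 0.0606), whereas Y passed in the opposite direction, at 0.437, 0.171 and 0.589 in baits 1, 2 and 5 (adjusted p = 1.24e-06, 2.15e-06 and 1.55e-05). For bait 2 the p from the draws was 1e-05 in ligated replicate 2 by itself and 1e-05 without merging, each the smallest the draws can give, and 0.0143 against chromosome length. For bait 3 it was 0.0337 with at least 2 reads.

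**Figure D4:**
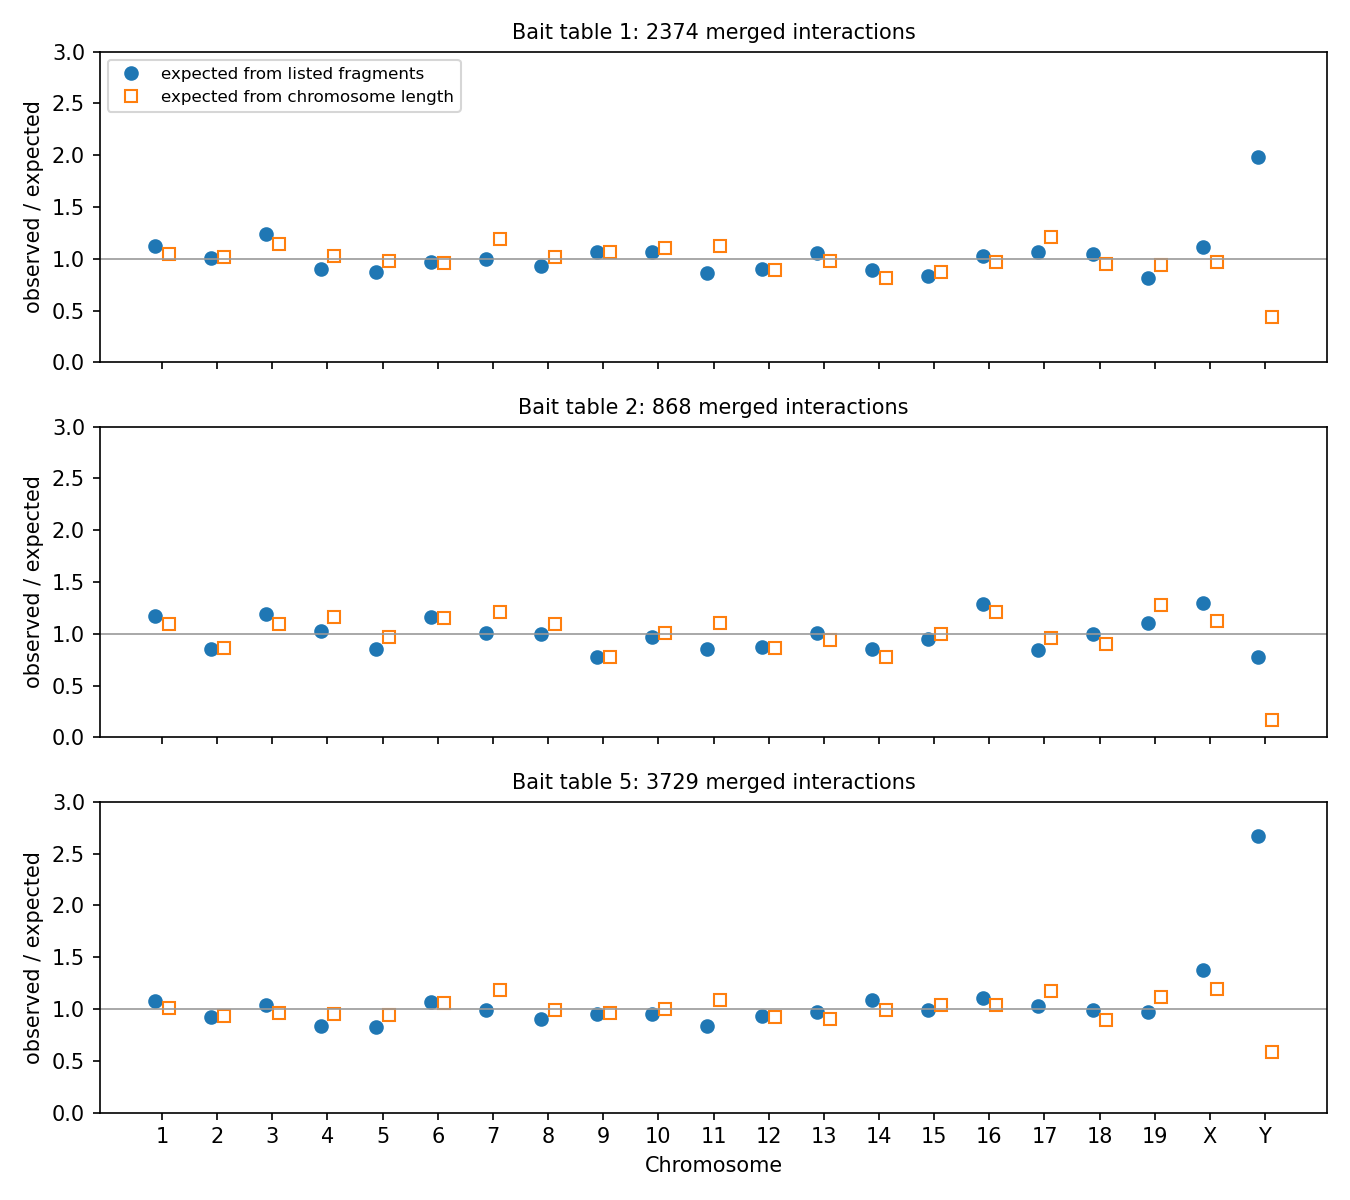
Observed over expected numbers of merged interactions (y axis) per chromosome (x axis) in baits 1, 2 and 5, with the expectation taken from listed fragments (filled blue circles) or from chromosome length (open orange squares). Y stands at 1.98 in bait 1 and 2.67 in bait 5 against listed fragments, and at 0.437 and 0.589 against length.

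Whether different baits met the same nuclear fragments was tested on reproducible fragments. Of the 31 fragments shared by 3 baits, 13 lay on chromosome 17 between 39843136 and 39847923, in or next to Rn18s-rs5, which has ribosomal RNA sequence, and 12 on chromosome 6 between 47654892 and 47681769, around the small RNA gene Rn4.5s and predicted genes such as Gm40367. The others included both fragments in Cmss1 and Filip1l, 1 at Chkb, which encodes a choline kinase (36 and 36 reads in bait 1, but 1 and 5 in bait 2 and 2 and 2 in bait 5), the 114-bp NUMT fragment in Myo3a, and those on chromosome 2 at 98666262 and chromosome 14 at 91590065 without a gene. The ribosomal locus had 2186 ± 1433 CPM after ligation in bait 1, 2580 ± 2565 in bait 2 and 1558 ± 1508 in bait 5 (SD, n = 2), and 0, 1 and 0 unligated reads. Baits 1 and 2 shared 68 fragments against 19.0 for independent lists (3.58 times, adjusted Fisher's exact p = 1.90e-18). Baits 1 and 5 shared 227 against 82.0 (2.77 times, adjusted p = 4.05e-41) and baits 2 and 5 shared 99 against 29.3 (3.38 times, adjusted p = 1.45e-24). Baits 2 and 3 shared 2 fragments (adjusted p = 0.0188) and baits 2 and 4 shared 1 (adjusted p = 0.0248), and both pairs included a NUMT fragment in Myo3a. In total 308 fragments were shared by exactly 2 baits, and 0 by 4 or 5. With at least 2 reads per replicate 88 fragments were shared by 2 or more baits, against 339, while the ratios for baits 1 and 2, 1 and 5, and 2 and 5 were 21.1, 9.28 and 15.2. With at least 10 reads they were 161, 30.9 and 72.9, and without fragments of recurrent length 5.45, 3.66 and 5.55. Without the ribosomal, the Rn4.5s and the chromosome 2 locus these ratios were 2.18, 2.17 and 2.54. In single replicates the ratios fell below 1 (0.583 to 0.652), as the background of detected fragments brings about. Fragments seen in the unligated library were also shared, with 6 against 0.291 for baits 1 and 2 (adjusted Fisher's exact p = 5.84e-06), 7 against 1.15 for baits 2 and 5 (adjusted p = 0.000484) and 3 against 0.999 for baits 1 and 5 (adjusted p = 0.132). These ratios of 20.6, 6.11 and 3.00 rest on few fragments, among them NUMT fragments. The Gm10925 fragment had 2, 2 and 139 unligated reads in baits 1, 2 and 5. The Myo3a fragment at 22589248 had 110, 4232 and 4, and the chromosome 12 NUMT had 1 in each of these baits. Reproducible fragments had 0 unligated reads by definition, so their ratios are not comparable with these. Since fragments were also shared without ligation, sharing between baits does not by itself show contact.

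Reproducible fragments lay in genes less often than listed fragments did. A gene was overlapped by 48.0% of them in bait 1 (exact 95% interval 46.2 to 49.8%), 50.6% in bait 2 (47.6 to 53.6%) and 47.5% in bait 5 (46.0 to 48.9%), against 57.0% of all listed fragments. The odds ratios were 0.694 (adjusted Fisher's exact p = 9.20e-23), 0.772 (6.04e-05) and 0.675 (1.99e-39). Protein-coding genes gave 0.714, 0.714 and 0.655, and lncRNA genes 0.838, 0.942 and 0.812. Pseudogenes were overlapped more often in bait 5 (odds ratio 1.29, adjusted p = 0.0404), and bait 3 had 12 of 21 fragments in genes (odds ratio 1.01, adjusted p = 1). The direction turned with depth per fragment in baits 1 and 5, but the background kept listed fragments of any read number. The turn can therefore also reflect that fragments with more reads differ from those with few. Fragments with at least 2 reads in each replicate lay in genes in 66.7%, 64.2% and 70.2% of cases (odds ratios 1.52, 1.36 and 1.78), and those with at least 10 reads in 73.6%, 57.4% and 74.0% (2.11, 1.02 and 2.16, with Fisher's exact p = 1 in bait 2). By fragment midpoint bait 2 had odds ratios of 1.10 at 2 reads (Fisher's exact p = 0.454) and 0.871 at 10 reads (p = 0.682). Fragments with at least 2 reads held fewer recurrent lengths (11.4%, 8.36% and 13.6%, against 25.8% of those listed), and without these lengths, where 64.5% of listed fragments lay in genes, the odds ratios at 2 reads were 1.27 (Fisher's exact p = 0.00165), 1.09 (p = 0.588) and 1.58 (p = 1.81e-11). By midpoint 57.8%, 66.1% and 64.2% of the fragments of the unligated libraries lay in genes, against 55.3% of those listed. Without fragments of recurrent length the odds ratio was 0.811 in bait 1 (Fisher's exact p = 1.19e-05), 0.895 in bait 2 (p = 0.164; 0.751 by fragment midpoint, p = 0.000216) and 0.802 in bait 5 (p = 7.91e-08), and with replicate 2 alone it was 1.06 in bait 1.

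**Figure D5:**
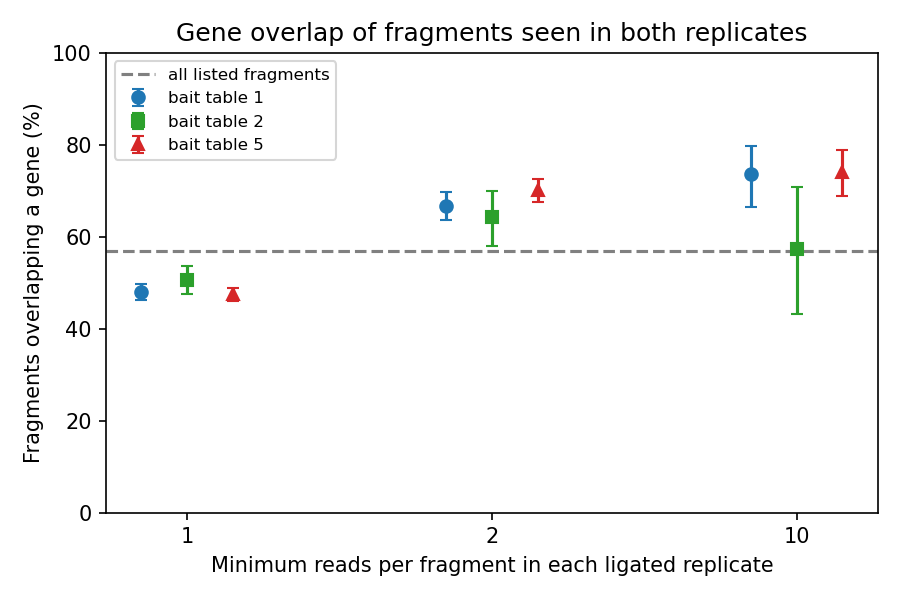
Percent of reproducible fragments that overlap a gene (y axis) by the minimum number of reads required in each ligated replicate (x axis) for bait 1 (blue circles), bait 2 (green squares) and bait 5 (red triangles), with exact 95% binomial intervals as bars and the share of all listed fragments as a dashed line at 57.0%. All 3 baits lie below the line at 1 read and above it at 2 reads.

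Nuclear genes of mitochondrial function were the main question of the gene lists. Of 80 OXPHOS genes, 12 were contacted (15.0%, against 13.5% of all protein-coding genes, odds ratio 1.13, adjusted one-sided Fisher's exact p = 0.634). Atp5g2, which encodes subunit c of ATP synthase, was contacted by bait 1 (7 and 6 reads) and bait 5 (62 and 62), and Cycs, which encodes cytochrome c, by bait 1 (9 and 2) and bait 5 (10 and 137). Further contacted members were Ndufs1 of complex I (bait 5, 15 and 130 reads) and Cox6c (bait 5, 10 and 10). Of 83 genes of the mitochondrial ribosome and translation, 12 were contacted (odds ratio 1.09, adjusted p = 0.634), among them Mrps28, Mrps36 (bait 5, 12 and 81 reads) and Mrpl41 (bait 1, 9 and 30). The 39 matched genes of mtDNA maintenance had 3 contacted members (odds ratio 0.535, adjusted p = 0.945), all by bait 5: Polg2, the accessory subunit of the mtDNA polymerase (24 and 29 reads), Clpx (8 and 8) and Atad3a (8 and 8). Of 33 matched genes of biogenesis and dynamics, 7 were contacted (odds ratio 1.73, adjusted p = 0.491), including the deacetylase Sirt3 (bait 5, 42 and 13 reads), the import receptor Tomm70a (bait 2, 13 and 46) and the fission gene Fis1 (bait 1, 17 and 7). None of these 4 lists passed. With replicate 2 alone all 4 did, at odds ratios of 3.01, 2.81, 2.92 and 13.7 and adjusted one-sided Fisher's exact p of 0.000495, 0.000590, 0.0155 and 0.000386, and with replicate 1 alone at 0.720, 0.977, 0.526 and 1.12 none did. Random lists matched on listed fragments were not drawn for single replicates. With both replicates, 84.5%, 70.6%, 11.7% and 61.5% of matched random lists had fewer contacted genes than the OXPHOS, ribosome, maintenance and biogenesis lists.

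Among the other lists, long neuronal and synaptic adhesion genes stood out, with 24 of 30 contacted (odds ratio 25.9, adjusted one-sided Fisher's exact p = 3.08e-15). Matched random lists had 14.3 contacted genes on average, and 99.98% of them had fewer than 24. The 24 genes had a median length of 1.52e+06 bp, and matching on deciles leaves differences in size within a decile. Whether gene size alone accounts for the excess was not tested. Csmd3, Dlg2, Dpp10 and Lsamp were contacted by baits 1, 2 and 5, but mostly by fragments with few reads: Dlg2 had 1 and 1 on its best fragment and Csmd3 had 3 and 4. Of the 24 genes, 9 had a fragment with at least 2 reads in each replicate (odds ratio 5.80), and 72.1% of matched random lists had fewer. Without fragments of recurrent length 15 were contacted (odds ratio 7.85), while 89.2% of matched random lists had fewer and 94.6% had as few or fewer. Cytosolic ribosomal protein genes had 15 of 64 contacted (odds ratio 1.97, adjusted p = 0.105), more than 88.3% of matched random lists, among them Rps25 (bait 5, 13 and 18 reads) and Rps15 (bait 1, 20 and 17). With at least 2 reads per replicate 12 of these 64 were contacted (odds ratio 3.13, adjusted one-sided Fisher's exact p = 0.00646), and the list also passed with either replicate alone (odds ratios 2.24 and 5.07, adjusted p = 0.00561 and 0.000112). Over its alternatives the adjusted p ran from 0.000112 to 0.582. Astrocyte genes had 5 of 30 contacted (adjusted p = 0.634), led by the transcription factor gene Nfia (bait 1, 5 and 110 reads) and including Aldh1l1 (bait 5, 4 and 39). Neuron genes also had 5 of 30 (adjusted p = 0.634), led by Gad1, a gene of GABA synthesis (bait 1, 32 and 62 reads), and passed with replicate 2 alone (odds ratio 3.86, adjusted p = 0.0154). Oligodendrocyte genes had 3 of 20 (adjusted p = 0.647) and microglia genes 1 of 20, Spi1 (adjusted p = 0.945).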

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

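The settings without NUMT fragments, without recurrent lengths and with fragments of any table as background were chosen after seeing the data. Apart from the shares of nuclear reads, there were 245 alternatives over 36 results. Of these, 172 kept the side of the threshold or, for counts, stayed within 1.5 times, and 29 moved a count further. Another 25 reversed a direction where the main or the alternative setting passed, 11 brought a result past the threshold and 8 took it back. A direction that turned where neither setting passed was counted as kept, as for OXPHOS genes (odds ratio 1.13, but 0.720 with replicate 1 alone). The shares of nuclear reads have no test, and their 25 alternatives show no stability, since leaving out 1 of 2 replicates cannot move a mean beyond their SD. With a single replicate they were 35.4 to 76.0%, 18.0 to 73.2%, 10.0 to 23.6%, 3.21 to 10.1% and 14.5 to 53.1% in baits 1 to 5. The share in bait 3 went from 16.8% to 9.63% without NUMT fragments, and that in bait 4 from 6.68% to 3.79% at 2 reads, 2.55% at 10 reads and 4.37% without NUMT fragments. The numbers of fragments seen in both ligated replicates fell with the minimum, by construction: at least 2 reads left 928 in bait 1, 260 in bait 2, 6 in bait 3 and 1243 in bait 5, and at least 10 reads left 182, 54, 3, 1 and 312 in baits 1 to 5. Without recurrent lengths 1895, 693 and 2535 remained in baits 1, 2 and 5, and without NUMT fragments 0 in bait 4. A single replicate gave 19100 to 52110, 6079 to 51380, 251 to 10202, 23 to 168 and 22422 to 66639 in baits 1 to 5. Fragments of 2 or more baits numbered 88 at 2 reads, 14 at 10 reads, 214 without recurrent lengths, and 2316 to 29391 with a single replicate. The ratio of shared fragments in single replicates was 0.605 to 0.630 for baits 1 and 2, 0.636 to 0.652 for baits 1 and 5 and 0.583 to 0.608 for baits 2 and 5, below 1 because the background holds only detected fragments. The overlap of the replicates relative to independent lists was 1.502 in bait 3 and 176.5 in bait 4 at 10 reads, 6.79 in bait 4 at 2 reads, and 1.60 in bait 3 and 90.8 in bait 4 on fragments of any table, or 1.23 in bait 3 and 0 in bait 4 there without NUMT fragments. Without the filter on low counts edgeR called 1 fragment in bait 3. For the distribution over chromosomes, p was 0.0956 in bait 1 and 0.103 in bait 5 on autosomes only, 0.232 in bait 5 and 0.0337 in bait 3 at 2 reads, 0.715 in bait 1 at 10 reads and 0.698 in bait 1 without recurrent lengths. In bait 2 it was 0.0143 by chromosome length, 1e-05 without merging, and 1e-05 to 0.198 with a single replicate, where 1e-05 is the smallest the draws can give. The odds ratio of lying in a gene was 1.52, 1.36 and 1.78 at 2 reads and 2.11, 1.02 and 2.16 at 10 reads in baits 1, 2 and 5, 0.895 in bait 2 without recurrent lengths, 1.27, 1.09 and 1.58 at 2 reads and 1.501, 0.726 and 1.64 at 10 reads without recurrent lengths, and 0.855 to 1.06 in bait 1 with a single replicate. The odds ratio of the cytosolic ribosomal list was 3.13 at 2 reads and 2.24 to 5.07 with a single replicate. With a single replicate it was 1.12 to 13.7 for biogenesis and dynamics, 0.977 to 2.81 for the mitochondrial ribosome, 0.526 to 2.92 for mtDNA maintenance, 1.53 to 3.86 for neuron genes and 0.720 to 3.01 for OXPHOS. Where the construction is not named, the cause was not tested. No paired analysis was possible because the unligated group has 1 library without a replicate number, so the groups share fewer than 2 numbers. The edgeR test with a replicate left out was not run, since 1 library against 1 leaves no residual degrees of freedom. In bait 4 neither DESeq2 and the other edgeR filters nor the chromosome test gave a value. The long neuronal list had no finite odds ratio with a single replicate, since all 30 genes were then contacted. Depth limited bait 4 most, with 63 unligated reads.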

Other observations

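The tests on NUMT reads, on fragments of recurrent length and on sharing between replicates were chosen only after the result was seen, whereas the minimum of 2 reads was not. Among fragments with at least 2 reads in each ligated replicate, OXPHOS genes kept 10 of their 12 contacted members, against 6.91% of all protein-coding genes (odds ratio 1.93, adjusted one-sided Fisher's exact p = 0.161). Of matched random lists 98.9% had fewer than 10, against 84.5% with fewer than 12 at 1 read and 89.6% without recurrent lengths. Besides Atp5g2, Cycs, Ndufs1 and Cox6c, the members included Ndufs3 of complex I (bait 5, 3 and 63 reads), Ndufv3 (bait 1, 4 and 32), the complex II subunit Sdhc (bait 2, 20 and 4) and Cox7a2l (bait 1, 3 and 84). For the cytosolic ribosomal proteins 99.2% of matched random lists had fewer than 12 contacted genes, against 88.3% at 1 read and 92.2% without recurrent lengths, with Rpl31 (bait 1, 6 and 17 reads), Rps19 (bait 5, 7 and 7) and Rpl34 (bait 1, 3 and 24) among them. The mitochondrial ribosome list had 6 of 83 at this minimum, and 60.3% of matched random lists had fewer. The mtDNA maintenance list had 3 of 39 and the biogenesis list 4 of 33, with 54.6% and 61.7% of matched random lists below. These percents were not adjusted over lists and settings. Random lists were matched on the number of listed fragments, not on the reads these carried.

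NUMT fragments such as those in Myo3a and Gm10925 carried similar read numbers in both ligated replicates, unlike other nuclear fragments. Contact as the only source of the reads was argued against for the Myo3a fragment at 22589248 in bait 2, which held 62.99% of the unligated reads and at most 3.40% of the ligated reads, whereas the 387-bp Myo3a fragment of that bait was higher after ligation (2233 CPM unligated, 9984 and 4361 ligated). Elsewhere contact cannot be told apart from mtDNA reads placed at NUMT copies. Within 10 kb of the loci 1 fragment without a NUMT was listed, and such neighbours held 0.0454% as many reads as the NUMTs. Fragments without reads were not listed and no digest was used, so how many neighbours could have held reads is not known. Placement stays open as well, since the 387-bp Myo3a fragment held 45.5% as many reads as the COX1 fragment of equal length in replicate 1 of bait 3 and 0.0236% in bait 5, and which end of a fragment a bait reads was not given. No biological explanation beyond contact was tested.

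With 1 read per replicate as the minimum, fragments with reads in both replicates lay less often in genes in baits 1, 2 and 5, and more often on Y in baits 1 and 5, on X in bait 5 and in long neuronal genes such as Dlg2 and Lsamp, whereas at 2 reads the odds ratios of lying in a gene were 1.52, 1.36 and 1.78 (1.27, 1.09 and 1.58 without recurrent lengths) and X stood at 0.4996 and 0.579 times its share in baits 1 and 5. The values at 2 reads were set against listed fragments of any read number. Recurrent lengths held 64.4%, 65.7% and 69.1% of fragments with 1 read in each replicate in baits 1, 2 and 5, against 25.8% of those listed, so reads of repeats placed over many copies are a candidate explanation. For long neuronal genes it may account for part, since 15 were contacted without recurrent lengths and 94.6% of matched random lists then had as few or fewer, just under a bound of 95% set after the result. The odds ratio was still 7.85, but against protein-coding genes of all sizes. For genes, recurrent lengths were not the whole cause in baits 1 and 5, with odds ratios without them of 0.811 (Fisher's exact p = 1.19e-05) and 0.802 (p = 7.91e-08), or 0.792, 0.751 and 0.751 by midpoint in baits 1, 2 and 5 (p = 7.52e-07, 0.000216 and 2.12e-12), but repeats of other lengths stayed in and cannot be told apart from other causes. For X and Y it stays open as well, since X in bait 5 (1.16) and Y in bait 1 (1.76) no longer passed while Y in bait 5 stood at 3.11, and no biological explanation was tested.

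The ligated replicates of a bait shared few nuclear fragments. That most of those shared were contacts of that bait alone was argued against in baits 1, 2 and 5, since replicates of the same bait overlapped at most 1.28 times as much as replicates of different baits (bait 2 without recurrent lengths, SE 0.0646). This does not extend to bait 3, with 18 shared fragments without NUMTs. Its overlap was 1.23 times that of independent lists, against 0.360 to 0.580 for its pairs with baits 1, 2 and 5 across libraries. That some were contacts of bait 2 alone may hold, since this ratio of 1.28, the highest of the 3 baits, lay above 1 by more than 2 SE (1.15 to 1.41). Mispriming by the primers of bait 2 would raise this ratio as well, so it does not show contact. Of 242 nuclear fragments in the unligated library of bait 2, 229 also had reads in ligated replicate 2, but only 35 in replicate 1. Of the 1117 fragments shared by the replicates of bait 2, 26 had unligated reads, in an unligated library of 6718 reads. The SE comes from leaving out chromosomes and does not measure the spread between technical replicates. Without recurrent lengths bait 5 also lay above 1 (1.07, 1.01 to 1.12), whereas the interval of bait 1 held 1 (1.053, 0.984 to 1.12). Sharing between baits can also come from the libraries themselves, and no biological explanation beyond contact was tested.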
